A study of Homo sapiens with 2 samples.

How the data were processed

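LSD1 ChIP-seq and input DNA were measured in PC-3M-luc cells, 1 library each, both labelled as biological replicate 1. Per the labels' protocols, the libraries were sequenced on an Illumina HiSeq instrument and mapped to hg19 with bowtie 2. The submitters' processing notes name MACS 1.41 and Bowtie2, and the builds hg19 and mm10. The cells are human and the peaks fit within the chromosomes of GRCh37, so mm10 was not used. Settings of the aligner and caller, duplicate handling, read numbers and the threshold on peaks were not given in the sources used here, so the depth behind each peak is unknown. The deposited peak list gives each peak's position and a score, and was taken as LSD1 called against input from the sample labels, which do not state it outright. The score was read as the peak caller's value of -10 × log10 p, from its lowest value of 50, its repeated value of 3100 and the caller named. That reading is from the values and no label states it, so the authors' score served only to rank, filter and describe peaks.

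The build was checked first. All 24 chromosome names of the list occur in GRCh37, 0 peaks run past a chromosome end, 4 touch an assembly gap, and 0 pairs overlap. Peak numbers run from 1 to 20110 without a break. The median width was 1649 bp (interval 1635 to 1665), from 347 to 36286 bp, and peaks cover 42 Mb, or 1.47% of the 2859 Mb of non-gap sequence. Genes came from GENCODE 44 mapped to GRCh37, with 20163 protein-coding genes and 146567 distinct start sites of their transcripts. Coordinates are 1-based.

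Each peak was placed by its midpoint, in the order promoter (within 1 kb of any TSS of a protein-coding gene), exon, intron and intergenic. Random placements kept each peak's width and chromosome and avoided gaps, 1000 times for the reported values and 100 times for alternatives. Clustering used a distance of 12.5 kb between midpoints. Densities have exact Poisson intervals and shares exact binomial intervals at 95%. The interval of the difference between the highest and the lowest of 4 equal groups by score is a normal approximation on 5028 peaks each. CpG-rich means a GC content over 55% and a CpG observed-to-expected ratio over 0.65 in the 1000 bp around a canonical TSS.

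The 11 gene lists were fixed before the data were examined, as were the named genes: the 10 peaks with the highest score with the nearest protein-coding TSS, the 5 promoters with the highest-scoring peak, KDM1A, PXN and LPAR6, up to 4 genes per list with the highest-scoring promoter peak, and the chromosomes of highest and lowest density, with ties resolved by width and position. Some genes of these lists are not reported here by name. Other genes are named in the text because they lack a peak or lie beside a fixed one, after their values were seen. A list's count was set against 10000 random lists drawn from all protein-coding genes, and its percentile counts ties as 50%. This describes the list and is no test across replicates. Motif shares were counted on both strands and set against flanks at 5 kb and against 1000000 random windows weighted to the peaks' GC content.

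The code was tested on simulated data. Random peaks gave a promoter fold of 0.999 and a clustering fold of 1.01 where 1 was planted, on 20110 peaks. A planted promoter share of 43.5%, which includes random peaks counted at promoters by the same code, came back as 43.5%. It checks that planted peaks are counted and is not an independent estimate. Of 1000 random lists, 4.8% fell outside the middle 95%, and 100% of 1000 lists with 21 of 24 members planted lay above it. A motif planted in 10% of 5000 sequences was found in 10%.

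Alternatives were peaks at or above the median score, peaks with a score of at least 100, removal of the widest 1%, a window of 5 kb, any overlap with 1 kb, the TSS of all genes, placement over the whole genome, lists matched on promoter GC, 5 kb for clustering, windows of 500 bp, GC-matched windows and density per gene. The canonical TSS alone was added after seeing the data. Uniqueness of promoters was the share of 32-base words found once in the reference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, numba 0.67.0, matplotlib 3.10.9 and samtools 1.23.1 were used.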

Results

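The series profiled the genomic binding of LSD1 (KDM1A, lysine-specific demethylase 1), a histone demethylase that removes methyl groups from mono- and dimethylated histone H3 lysine 4 and that works within corepressor complexes. The cells were PC-3M-luc, a luciferase-marked line derived from the metastatic PC-3M variant of the androgen-independent prostate carcinoma line PC-3. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) gave 1 LSD1 library, and 1 input library served as background. The authors' single list of 20110 peaks on 24 chromosomes was taken as LSD1 called against this input, and the read depth of either library was not given in the sources used here. With 1 library per arm no value below has a replicate check, and no p-value was computed across peaks or genes. Intervals on shares are exact 95% binomial (Clopper-Pearson) and cover counting error only. A gene without a peak had none past the authors' threshold, which does not show absence of binding.

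The list was read for where LSD1 sat in the genome of metastatic prostate cancer cells and for whether genes of metastasis, adhesion and prostate identity lay under it. LSD1 peaks were concentrated at the promoters of protein-coding genes. Of the 20110 peaks, 11089 (55.1%, interval 54.5 to 55.8) had their midpoint within 1 kb of an annotated transcription start site (TSS), 9.69-fold over the mean of 1000 random placements (5.69%, range 5.24 to 6.26). Exons held 1504 peaks (7.48%), 2.41-fold over random. Introns held 3458 peaks (17.2%) against 40.4% at random, and intergenic sequence held 4059 (20.2%) against 50.8%. Promoter peaks were also wider and higher in score than the others, with a median width of 1823 bp against 1687 bp in exons, 1345 bp in introns and 1392 bp between genes, and a median score of 362 against 121, 85.2 and 119. The median peak lay 580 bp from the nearest TSS, and 17.8% of peaks lay more than 10 kb away. The fold depended on how a promoter was defined, from 3.81 with a window of 5 kb to 25.7 with the canonical TSS alone, a definition added after the data were seen.

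**Figure D1:**
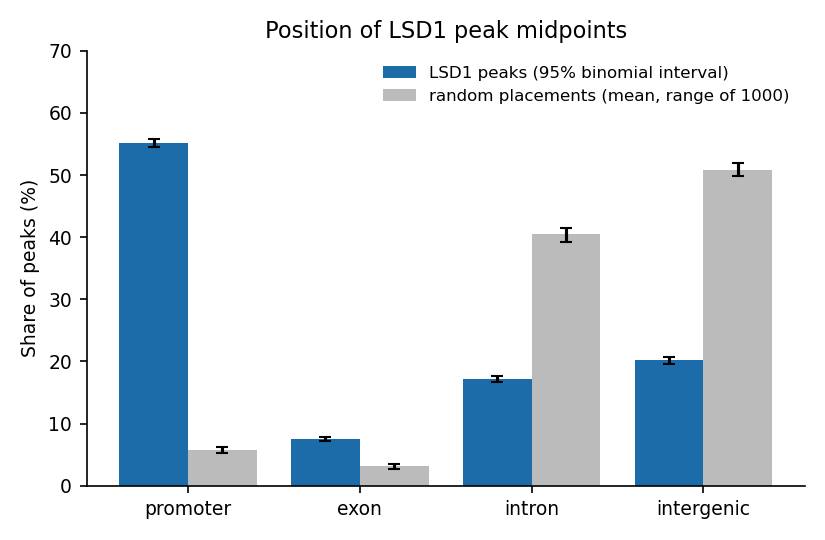
Share of LSD1 peak midpoints (y axis, %) at promoters, in exons, in introns and between genes, with 95% binomial intervals, beside the mean of 1000 random placements with their range. Promoters held 55.1% of the peaks against 5.69% at random.

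Peaks marked CpG-rich promoters far more often than CpG-poor ones. A peak reached within 1 kb of the canonical TSS at 8693 of 11280 CpG-rich promoters (77.1%, interval 76.3 to 77.8) and at 2370 of 8583 CpG-poor promoters (27.6%, interval 26.7 to 28.6). Among 20136 protein-coding gene symbols, 11018 (54.7%) had a peak midpoint within 1 kb of any annotated TSS. The grouping of promoters by CpG content was chosen after the data were seen.

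Of the 10 highest-scoring peaks, 7 had their midpoint at promoters of protein-coding genes. The score is the authors' value per peak and was used only to rank and describe peaks within this list. The highest score, 3226.07, belonged to an 11132 bp peak over the promoter of CD63, a tetraspanin of endosomes and exosomes (hg19 chromosome 12, 56113642 to 56124773). The next promoter peaks were at LCN2, a secreted iron-sequestering lipocalin (chromosome 9, 130910224 to 130917457, score 3206.76), at RPLP2, a protein of the ribosomal stalk (chromosome 11, 807696 to 814496, score 3205.62), at SGMS1, a sphingomyelin synthase (chromosome 10, 52381580 to 52386226, score 3204.94), and at FOXO3, a forkhead transcription factor (chromosome 6, 108878146 to 108882384, score 3192.04). Promoter peaks at BCAR3, an adaptor protein, and at POLR3E, a subunit of RNA polymerase III, scored 3184.65 and 3184.43. A 7663 bp peak over the TSS of RPL10A, a protein of the large ribosomal subunit, scored 3191.8, with its midpoint 2875 bp from that TSS (chromosome 6, 35435241 to 35442903). The remaining members of the top 10 were narrower and lay over small RNA genes inside or beside coding genes. A 1324 bp peak in an intron of TEX14 covered RNU1-85P, a copy of the U1 spliceosomal RNA gene (chromosome 17, 56756274 to 56757597, score 3197.22), and a 2055 bp peak nearest to TMEM107 covered SNORD118, the U8 small nucleolar RNA gene (chromosome 17, 8076155 to 8078209, score 3196.17). Exactly 3100 was the score of 206 further peaks and 19 peaks exceeded it, so the score does not rank those 206 among themselves. A value repeated this way may stand for a limit of the score, so the 206 cannot be placed below the 19 either. The median width was 6775.5 bp at 3100 and 4526 bp above it. The order of the top 10 is therefore that of the printed score alone.

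The demethylase gene itself and PXN carried LSD1 peaks, and LPAR6 did not. These genes were fixed as items of interest because the study concerns metastasis, in which PXN, the focal adhesion scaffold paxillin, and LPAR6, a lysophosphatidic acid receptor, have roles. KDM1A (chromosome 1, 23345936 to 23410182, plus strand) had 1 peak, over its promoter (23345114 to 23347203), with a score of 877.5. PXN (chromosome 12, 120648242 to 120703574, minus strand) was overlapped by 11 peaks, some of them almost adjoining and counted as called. The highest-scoring of them, at 1934.88, was 5077 bp wide and covered the canonical TSS at 120703533 (120699151 to 120704227). A second PXN peak, with a score of 1252.11, lay in the gene body at 120665306 to 120671172, and the promoter peak picked by the midpoint criterion, at an alternative TSS near the 3′ end, spanned 120650948 to 120655444 with a score of 773.36. No peak overlapped LPAR6 (chromosome 13, 48963703 to 49018840, minus strand), a gene nested in an intron of the tumour suppressor RB1. On the side of lower coordinates, the nearest peak to LPAR6 was 85303 bp away, at the RB1 promoter (48877121 to 48878399, score 697.34). On the side of higher coordinates it was 87265 bp away (49106106 to 49107764, score 517.69).

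**Figure D2:**
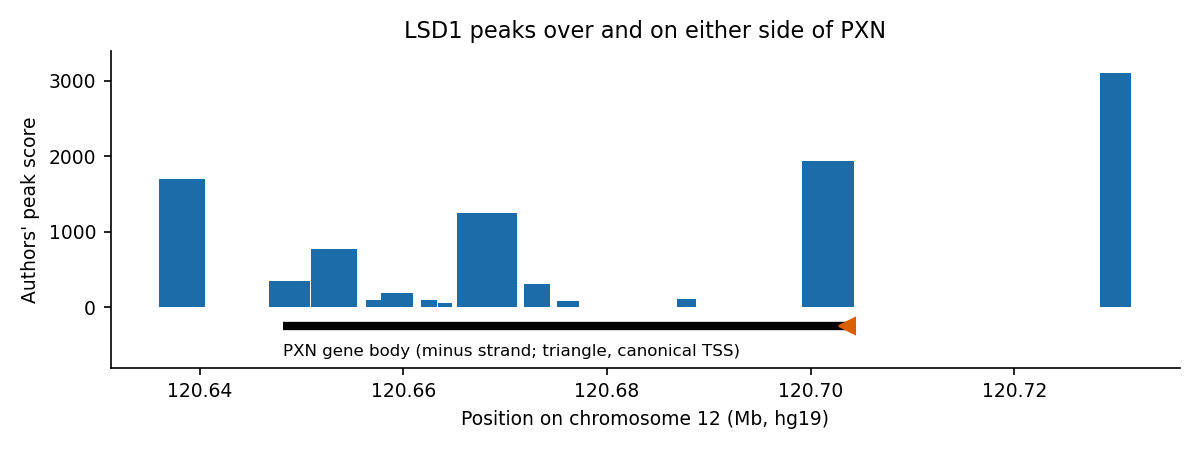
LSD1 peaks over PXN and the nearest peak on either side, drawn to scale along hg19 chromosome 12 (x axis, Mb) with the authors' score as height (y axis, no unit). Of the 11 peaks over the gene body (black bar), the one at the canonical TSS (triangle) had the highest score, 1934.88.

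Genes of the LSD1 complexes, of epithelial-mesenchymal transition (EMT) and invasion, of the cell cycle and of the ribosome had promoter peaks more often than random gene lists of the same size. Of 23 genes encoding LSD1 and its partners, 21 had a peak, against a median of 13 in 10000 random lists (percentile 99.985). Scores given for list members here and for the other lists are the highest among peaks that met the midpoint criterion, and wider peaks centred further from the TSS exceeded them at some members, such as RCOR1 (3100) and PXN. In the list of LSD1 complexes these were at GSE1 (3041.32) and RCOR3 (1148.94), which encode components of the CoREST-type complexes, at MBD3, a subunit of the NuRD complex (2733.01), and at CTBP2, a corepressor (1143.66). The CTBP2 peak lay at an alternative TSS and did not cover the canonical one. Among the EMT and invasion genes 23 of 28 had a peak against a random median of 15 (percentile 99.85), led by ESRP2, an epithelial splicing regulator (2842.33), SNAI1, a repressor of E-cadherin (1776.15), VIM, the mesenchymal intermediate filament vimentin (1711.79), and PLAU, the urokinase protease, whose gene lay under a peak of 18973 bp (1437.14). The members without a peak were FN1, MMP1, MMP2, MMP9 and SPARC. Cell cycle genes had a peak at 21 of 25 members (random median 14, percentile 99.86), with scores led by MCM7 (775.53) and MCM4 (560.57), both parts of the replicative helicase, PCNA, the polymerase clamp (577.62), and UBE2C, a mitotic ubiquitin-conjugating enzyme (473.5). Ribosomal protein genes had a peak midpoint at 19 of 24 promoters (random median 13, percentile 99.26), and 24 of 24 when any base of the peak counted. RPL8, RPS2 and RPL13 each had a score of 3100 and RPL7 had 3095.58. With the canonical TSS alone the ribosomal count was 10 and its percentile 22.3, although the canonical TSS of all 24 genes lay under a peak. Without the widest 1% of peaks the ribosomal percentile was 88.3, and the EMT and cell cycle lists stood at percentiles 96.8 and 91.5 with a score of at least 100, and at 66.8 and 56.9 at or above the median score.

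Developmental regulators and olfactory receptors lay at the other end. Of 22 developmental transcription factor genes 6 had a promoter peak against a random median of 12 (percentile 0.5), with scores of 1126.48 at WT1, 1039.7 at HOXA9 and 637.62 at GATA6. None of the 22 olfactory receptor genes had one (random median 12, percentile 0). Against random lists matched on promoter GC content the developmental list stood at percentile 0.06 and the olfactory list at 0.705. The developmental list moved to percentile 3.17 among peaks at or above the median score.

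The lists of prostate luminal, basal, neuroendocrine, adhesion and immediate early genes lay within the middle 95% of random lists. Prostate luminal genes had a peak at 10 of 20 members (percentile 33.6). The luminal keratin genes KRT18 (2687.24) and KRT8 (896.67), the pioneer factor gene FOXA1 (2070.94) and the transporter gene ABCC4 (484.73) led by the midpoint criterion, while KLK3, KLK2 and TMPRSS2 were among those with none. Neuroendocrine and neuronal genes had 9 of 21 (percentile 14), led by VGF, a secreted neuropeptide precursor (2302.09), with STMN3 (650.18), SYP (514.03) and BDNF (485.91). Basal epithelial genes had 7 of 15 (percentile 26.9), led by KRT15 (1070.97), LAMA3 (608.68), ITGB4 (539.25) and DST (408.42), with none at TP63, KRT5 or KRT14 promoters. Focal adhesion and lysophosphatidic acid receptor genes had 15 of 24 (percentile 78), led, by the midpoint criterion, by ACTN1 (1749.3), FLNA (915.71), BCAR1 (872.83) and PTK2 (867.35), all encoding proteins of the adhesion and actin machinery. Immediate early genes had 13 of 20 (percentile 81.4), with scores of 3100 at JUNB and JUND, 2527.57 at DUSP6 and 2490.96 at JUN. Counting any base of the peak within 1 kb raised the focal adhesion list to 19 of 24 (percentile 98.3) and the immediate early list to 19 of 20 (percentile 99.99), with MYC the member left without a peak. With the canonical TSS alone the focal adhesion list had 10 of 24 (percentile 22.6) and the basal list 4 of 15 (percentile 4.11). The peaks named at FLNA, BCAR1, KRT15, ITGB4, DST, STMN3 and BDNF lay at alternative TSSs and did not cover the canonical one.

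**Figure D3:**
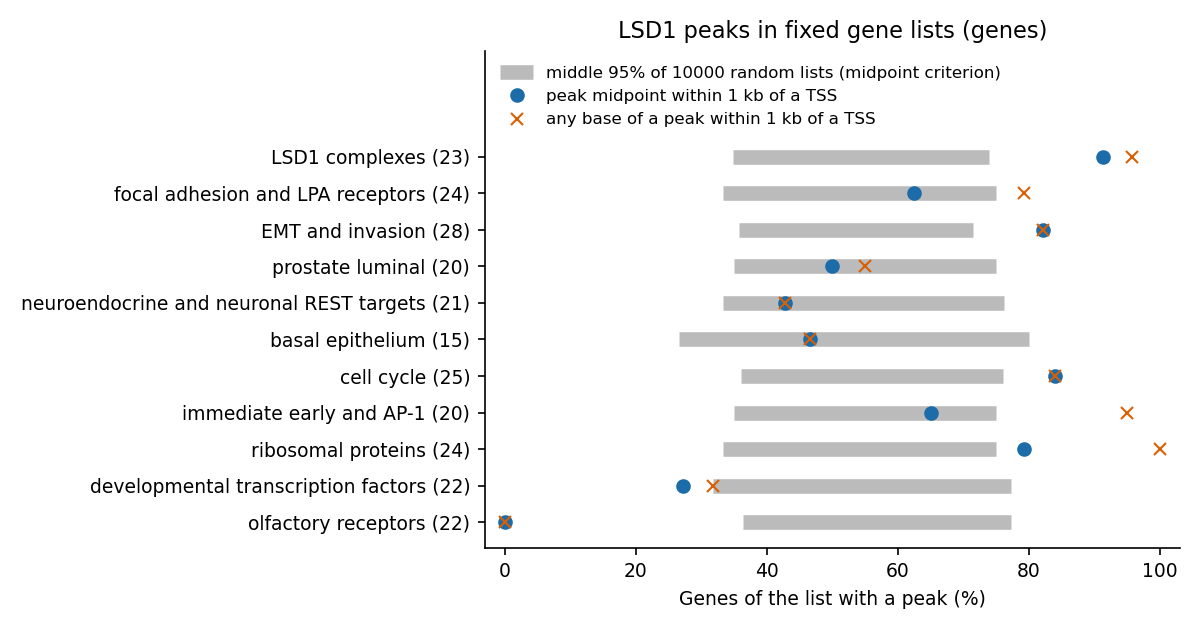
Share of genes in each of the 11 fixed lists with an LSD1 peak (x axis, %), by peak midpoint (circles) and by any base of the peak (crosses), with grey bars for the middle 95% of 10000 random lists by midpoint. By midpoint, 4 lists lay above and 2 below the grey bars.

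Chromosome 19, the most gene-dense chromosome, had the highest peak density, and chromosome Y the lowest. Chromosome 19 carried 1695 peaks, or 30.4 per Mb of non-gap sequence, 4.32-fold over the genome (exact Poisson interval 4.11 to 4.53). Chromosomes 17, 22 and 16 followed at 2.35-fold, 2-fold and 1.98-fold. Chromosome Y carried 1 peak (0.0435 per Mb), and the next lowest were chromosome 13 with 255 peaks (0.379-fold, interval 0.334 to 0.429) and chromosome X with 503 peaks (0.473-fold, interval 0.433 to 0.516). Per protein-coding gene the value of chromosome 19 was 1.15-fold (interval 1.09 to 1.2), below chromosomes 16 (1.28-fold), 20 (1.22-fold) and 14 (1.19-fold), while chromosome X stayed at 0.58-fold (interval 0.531 to 0.633). PC-3 derived lines have an abnormal karyotype, and copy number, including the presence of chromosome Y, was not analysed here.

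**Figure D4:**
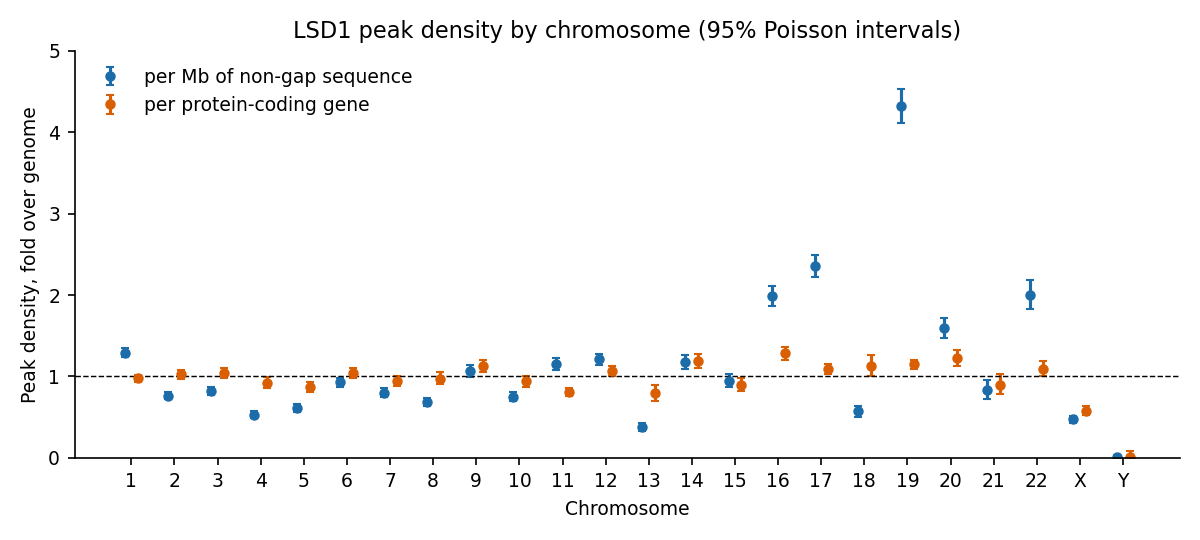
Peak density of each chromosome as a fold over the genome (y axis), per Mb of non-gap sequence and per protein-coding gene, with exact 95% Poisson intervals. Chromosome 19 stood at 4.32-fold per Mb and 1.15-fold per gene.

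LSD1 peaks lay in groups, and the stronger peaks were those at promoters. Of all peaks, 10802 (53.7%, interval 53 to 54.4) had a neighbour within the fixed clustering distance, 2.59-fold over random placements (20.7%, range 19.7 to 22.1). The placements did not keep peaks at promoters, so this fold is not separated from the grouping of start sites themselves. Closely adjoining peaks, as over PXN, were counted as separate neighbours. With the peaks divided by score into 4 groups of equal size, the promoter share was 26.1% in the lowest group, 43.9% and 73% in the middle groups and 77.6% in the highest, a difference of 51.5 percentage points between the extremes (interval 49.8 to 53.1). Median width was 1006.5 bp in the lowest group and 2681.5 bp in the highest. Among peaks at or above the median score the clustered share was 31.1%, at 2.84-fold over random.

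The sequence under LSD1 peaks was rich in GC and CpG, and the AP-1 and CTCF elements stood higher away from promoters than at them. The 200 bp at peak midpoints had a median GC content of 60% and a CpG observed-to-expected ratio of 0.629, against 47% and 0.314 in flanks at 5 kb. The median difference per peak was 11.3 percentage points (interval 10.8 to 11.5), and 80.2% of peaks exceeded their flanks. At promoters the CCGGAAGY element of ETS factors occurred in 5.74% of windows, 4.05-fold over random windows of equal GC, and the NRF1 element, GCGCATGCGC, in 0.712%, 3.17-fold. The random windows were matched on GC alone, while promoter windows had a CpG ratio of 0.762 against 0.298 in their flanks. Both elements contain CpG, so their folds are not separated from CpG content. In introns and between genes these elements were also above GC-matched windows, ETS at 1.87-fold and NRF1 at 3.96-fold, the latter from 14 windows. Among peaks in introns and between genes, the TGASTCA element of AP-1 (FOS and JUN dimers) occurred in 7.96% of windows, 2.62-fold over GC-matched windows, against 1.85% and 0.958-fold at promoters. The CTCF core stood at 3-fold in those same distal peaks, from 42 windows, and at 0.884-fold at promoters. The separation into promoter and other peaks was chosen after the data were seen.

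Over all peaks, 7 of the 16 motifs were at least 1.5-fold over flanks, with NRF1 at 27.4-fold from 96 peak windows and 7 flank windows, SP/KLF at 8.8-fold, ETS at 8.1-fold, CTCF at 3.29-fold, the MYC E-box at 1.91-fold and the androgen response element at 1.59-fold from 27 peak windows. The partial REST element occurred in 49 peak windows and 7 flank windows, 14-fold. In introns and between genes it stood at 3.21-fold over GC-matched windows, from 14 windows, and at promoters at 1.39-fold, from 32. Against GC-matched windows NRF1 fell to 3.28-fold, ETS to 3.43-fold, SP/KLF to 1.66-fold, the partial REST element to 1.72-fold and the MYC E-box to 1.26-fold. These elements all contain CpG, on which the random windows were not matched. CTCF fell to 1.54-fold, the androgen response element stood at 1.56-fold, and AP-1 rose from 1.46-fold over flanks to 1.78-fold. GATA and FOXA elements were below flanks, at 0.467-fold and 0.534-fold, and stood at 1.09-fold and 1.26-fold against GC-matched windows. Among peaks at or above the median score, of which 75.3% were at promoters, AP-1 stood at 0.721-fold over flanks. Over peaks of any score it stood at 0.662-fold at promoters and at 2.52-fold in introns and between genes. High-scoring peaks away from promoters were not counted separately, so score is not separated from position. The limit of 1.5-fold was set after the data were seen, and a motif marks sequence, not binding.

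**Figure D5:**
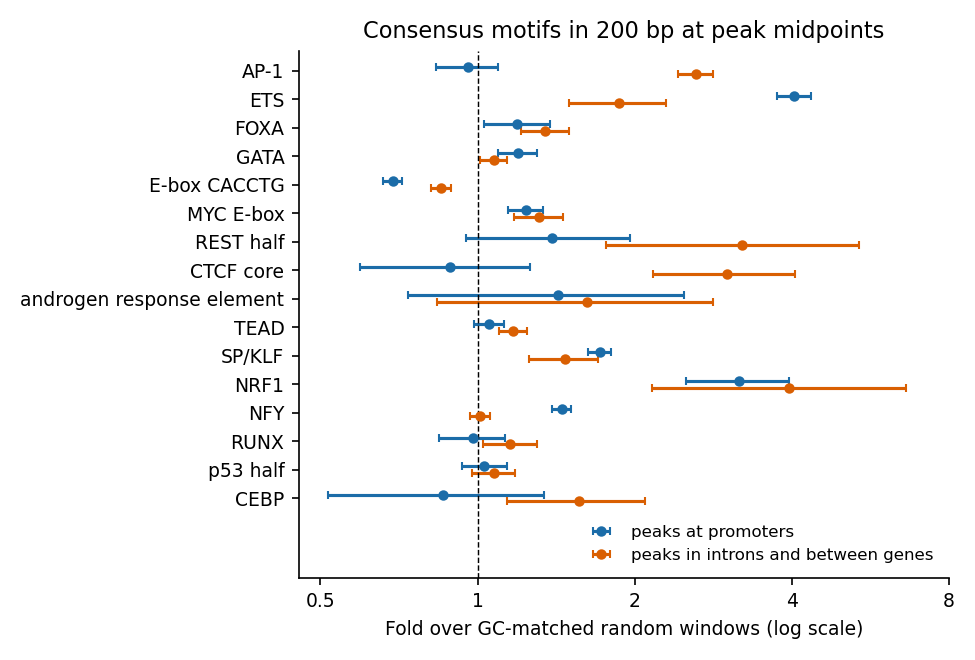
Fold of 16 consensus motifs in the 200 bp at peak midpoints over GC-matched random windows (x axis, log scale), for promoter peaks and for peaks in introns and between genes, with 95% binomial intervals of the peak share. AP-1 stood at 2.62-fold away from promoters and at 0.958-fold at promoters.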

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

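No paired analysis was possible because each arm had 1 library. The canonical TSS setting was chosen after seeing the data. Of 50 alternative values of the main results, 19 stayed within the counting interval (for counts, within 1.5 times) and 31 moved, none changing direction. Among other values, 160 stayed, 60 moved and 9 changed side, where a list percentile counts as staying if its place inside or outside the middle 95% did not change, however far it shifted within it. Peaks at or above the median score were wider (median 2214 bp), with promoter share 75.3% (13.3-fold), intergenic share 12.8%, clustered share 31.1% (2.84-fold), chromosome 19 at 3.94-fold, a GC difference of 17.3 points, 3 gene lists outside the middle 95% against 6, and AP-1 at 0.721-fold. A score of at least 100 gave 1973 bp, promoter share 67.2% (12-fold), intergenic share 16.5%, clustered share 40.6% (2.7-fold) and a GC difference of 14.8 points. These subsets hold fewer peaks and so fewer neighbours; the cause of the other shifts was not tested. The promoter share was 73.4% (3.81-fold) with 5 kb, 61.3% (6.18-fold) with any base of the peak, 60.9% (6.68-fold) with the TSS of all genes and 44.1% (25.7-fold) with the canonical TSS alone, by construction of the window, and the fold was 12.48 over the whole genome. The difference between the highest and lowest score groups was 35.7 points with 5 kb and 55.6 with any base. Clustering at 5 kb was 32.7% (3.57-fold). Chromosome 19 was 1.15-fold per gene. The GC difference was 10.3 points in 500 bp windows. The ribosomal percentile was 22.3 with the canonical TSS alone. Against GC-matched windows 7 motifs crossed 1: FOXA 1.26, GATA 1.09, TEAD 1.11, NFY 1.21, RUNX 1.06, the partial p53 element 1.07 and CEBP 1.23 (the cause was not tested). Unknown read depth limits which weak peaks were called.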

Other observations

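The gene families, small RNA genes, neighbouring promoters and peak-free stretches described here were chosen after the data were seen, as were the tests of a chance run and of a missing region, and the widths of single ribosomal protein peaks had been seen before their test. Genes of the ribosomes, the proteasome and translation initiation carried LSD1 peaks more often than protein-coding genes at large, and histone genes did not clearly so. Families were taken by the form of the gene symbol. Genes that share a symbol stem but not the function, as under PSM and EIF, may therefore be included. Any overlap with the window counted, which favours wide peaks, and the families were not counted by midpoint. By midpoint at the canonical TSS, the fixed list of 24 ribosomal protein genes had 10 (percentile 22.3), although all 24 canonical TSSs lay under a peak. Background over heavily transcribed genes, raised below for wide peaks, was not separated here. A peak reached within 1 kb of the canonical TSS at 77 of 78 mitochondrial ribosomal protein genes (98.7%, interval 93.1 to 100), 81 of 86 cytosolic ribosomal protein genes (94.2%), 43 of 45 proteasome subunit genes (95.6%) and 49 of 56 initiation factor genes (87.5%, interval 75.9 to 94.8), with 39 of 58 histone genes (67.2%, interval 53.7 to 79), against 55.7% of all protein-coding genes. Among CpG-rich promoters alone the shares were 97.9%, 98.4%, 100% and 91.7% for those first 4 families and 9 of 13 for histone genes, against 77.1% of all. CpG-rich promoters with a divergent partner within 1 kb had a peak in 1418 of 1469 cases (96.5%) against 7272 of 9806 (74.2%) for single ones, and a window that holds a pair of start sites has more chances to hold a peak. Each member of a divergent pair was counted as a case, so both can rest on the same peak. At the other end, 0 of 94 keratin-associated protein genes, 0 of 405 olfactory receptor genes, 1 of 51 clustered protocadherin genes and 17 of 95 KCN potassium channel genes (17.9%) had one. CpG content is not separated from family for the keratin-associated, olfactory receptor and clustered protocadherin genes, of which 0, 1 and 2 had a CpG-rich promoter. CpG-rich KCN promoters had a peak in 15 of 52 cases (28.8%). In the HOX clusters, which encode body-axis regulators, 6 of 11 HOXA genes had a peak (interval 23.4 to 83.3), 1 of 10 HOXB genes (0.253 to 44.5), and 0 of 9 in each of the HOXC and HOXD clusters (0 to 33.6). Among CpG-rich promoters the counts were 6 of 9 in HOXA, 0 of 4 in HOXB, 0 of 6 in HOXC and 0 of 8 in HOXD. The intervals overlap, which does not settle whether the clusters differ, and that difference was not tested.

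Genes of functional small RNAs, among them spliceosomal, RNA polymerase III, small nucleolar and telomerase RNAs, were another group under the peaks. Of 29 listed functional genes found in the annotation, 25 were overlapped by a peak (86.2%, interval 68.3 to 96.1), with a median peak width of 2042 bp. Among 3920 other annotated snRNA and miscellaneous RNA genes, many of them inactive copies, 70 were (1.79%, interval 1.39 to 2.25). Uniqueness of sequence was not measured at these RNA genes. Loss of reads at repeated copies is therefore not separated from inactivity in this contrast. Any overlap counted, so a peak centred on a neighbouring promoter was also credited to the RNA gene. Of the 25, 8 had a score of 3100 or more, among them RNU1-1 (U1), RNU4-1 and RNU4-2 (U4, under the same peak), RNU4ATAC of the minor spliceosome and SNORD118. RN7SK, the RNA that restrains P-TEFb, scored 239.46, RMRP 549.46 and TERC, the telomerase RNA, 936.06. RNU1-3, RNU1-4, SNORD3A and VTRNA1-3 had no peak.

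The pseudoautosomal regions of chromosome X had no peak at any of their 8 CpG-rich promoters, while 246 of 354 CpG-rich promoters elsewhere on X did (69.5%, interval 64.4 to 74.2). Reads matching their copy on chromosome Y too, which is masked in the reference used here and so invisible to the count of unique words, may have been left unassigned. CpG-rich promoters outside these regions, with under 50% of their 32-base words unique, had a peak in 17% of cases (26 of 153, interval 11.4 to 23.9), against 76.7% (interval 75.9 to 77.6) where at least 90% were unique, consistent with such a loss. The class between these, which holds ARSD, stood at 84.8% (interval 83 to 86.4), so the share did not fall gradually with uniqueness. The run without peaks goes on past the boundary through GYG2, ARSD and MXRA5, with 97%, 84.8% and 94.9% unique words, so this loss does not account for the whole run, and no biological explanation was tested.

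The 1 peak on chromosome Y lay at 21154105 to 21155156, where 45 of 52 words were found once in the reference. That count covers only sequence present in the reference, so it does not show that the reads came from chromosome Y. Whether these cells carry chromosome Y was not analysed.

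A stretch of 469 kb on chromosome 17 (40202768 to 40671667) held no peak at 7 CpG-rich promoters, among them STAT3, STAT5A and STAT5B, transcription factors of cytokine signalling, RAB5C and CAVIN1. Repeated sequence is argued against, since the median share of unique words at these promoters was 99%. A chance run stays open: 5 of 1000 shuffles of peak status along the chromosome gave a run of 7, but the stretch was picked for being empty, and longer runs lay on chromosome X (11 promoters), from ZNF582 to ZIM2 on chromosome 19 (10), from HOXC13 to PPP1R1A on chromosome 12 (8) and in the HOXD cluster (8). A region missing from the genome of these cells, as reported for STAT3 in PC-3, may explain it, and the density of chromosome 17 would give 7.76 peaks in the stretch. This too stays open for the same reason, and a block of inactive genes was not tested.

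Some peaks spanned whole gene bodies, such as those over ERRFI1 (25320 bp), a feedback inhibitor of EGFR, ENO1 (25073 bp), a glycolytic enzyme, and STC2 (21890 bp), and a 36238 bp peak covered the non-coding RNA gene NEAT1. For the widest 1% of peaks, several promoters merged under one peak are argued against as the main source. Of these 202 peaks, 51 (25.2%, interval 19.4 to 31.8) covered the canonical TSSs of 2 or more protein-coding genes. A further 110 covered 1 such TSS and 41 covered 0. The 202 were picked by width and not for spanning a gene body, so narrower peaks over short genes were not tested. Background over heavily transcribed genes remains a candidate explanation: ribosomal protein genes had a median of 90.6% of their body under peaks, at percentile 99.99 of random lists of genes with a peak at the TSS matched on length (median 39.7%). LSD1 spreading with active transcription would give the same value, and no biological explanation was tested.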
